A study of Mus musculus with 6 samples.

How the data were processed

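Single-cell RNA libraries of mouse bladder tumours were analysed, 3 from tumours induced in basal urothelial cells and 3 from tumours induced in luminal urothelial cells. Per the labels, the libraries were droplet libraries of the transcripts' 3' ends. Per the submitters' processing notes, reads were counted with STARsolo on the mouse build mm39; versions and settings are not given in the sources used here. The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, each library on its own and without normalization per the file headers. Each matrix lists 42645 features. In the deposited gene names, 126 nuclear genes carried a mitochondrial-style text inserted into their symbol; 117 of these were restored by matching to the reference gene table, whose assembly is GRCm38.p6, and 9 were not matched. That table was used only for names and for which genes neighbour each other, since its assembly is not the build of the counts.

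The replicate numbers follow the order of deposition and pair nothing, and nothing in the labels says that the libraries of a group came from separate mice, so p-values measure the spread between these samples only. The labels also carry a library number, which falls into a lower-numbered series (basal-induced 1 and 2, luminal-induced 3) and a higher-numbered series (basal-induced 3, luminal-induced 1 and 2). What the number means is not stated, and values are given within each series for shares of classes, states and cycling cells. For genes the series entered as a covariate in an alternative fit. No 2 libraries held like counts: over genes with at least 10 counts in each of a pair, chi-square per degree of freedom ran from 73.0 to 466, and between 0 and 7 barcodes were shared.

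Cells with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 15392 of 15903 barcodes. Scrublet marked 20 of these cells (0.130%), too few for a working doublet call, so 434 cells with markers of urothelium together with markers of fibroblasts, immune cells or endothelium were left out instead, a rule chosen after the data were seen. With the cells Scrublet marked also left out, 14948 cells remained. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at a resolution of 0.5 were used (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). A cluster was called urothelial-like where at least 75% of its cells held 8 or more UMIs per 10000 of 6 epithelial genes. The other cells were clustered again, and clusters were named from fixed markers; a cluster with more markers of another class than of its own among its 10 leading genes stayed unnamed. Another 440 cells with epithelial genes outside urothelial-like clusters were set aside from every class. All of these thresholds were set after the data were seen.

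Counts were summed per library and class and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, limma 3.58.1, R 4.3.3), as basal-induced minus luminal-induced. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A class was tested where at least 2 libraries per group held 20 or more of its cells. The class tests, the gene lists, the markers, the rule for named genes and the alternatives not named as added later were fixed before the data were examined. The endothelial-like test was added after the data were seen. CPM values are scaled to the library's total in a class, after TMM scaling in the gene tests and without it where a value is given for several classes. Standard deviations (SD) are over libraries, and SE is the standard error of the fitted log2 fold change.

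Named genes are the 10 with the largest absolute log2 fold change in each direction among called genes with an average log2 CPM of at least 4 and no overlap between the groups' libraries. Where fewer qualified, the remaining places went to the genes with the smallest p, given as values only. Predicted genes and immunoglobulin or T cell receptor segments were counted and not named by this rule. In other classes up to 5 genes per direction were named. Pten, Trp53, Krt5, Upk2 and any reporter feature were always named, and from each list up to 4 members with the smallest p. Genes outside this rule were chosen after their values were seen: Tpx2, Rrm1, Cd74, H2-Ab1, H2-Ea, Foxr1, BC023719, Gm8801, A930015D03Rik, Hmga1b, Rnaset2a, Sprr2a1 and Sprr2a2.

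Of 33 fixed lists with 524 matched genes, 31 could be tested in urothelial-like cells with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares of cells were compared with exact two-sided permutation tests; with 3 libraries against 3 there are 20 assignments, and the smallest p possible is 0.10. For states and cycling, each urothelial-like cell was thinned to 2000 UMIs, and 40 shallower cells of luminal-induced 1 were left out. A cell was keratin-positive with at least 1 UMI of Krt5 or Krt14, uroplakin-positive with at least 1 UMI of Upk1a, Upk2 or Upk3a, and cycling with at least 2 UMIs over the G2M list. These calls read free RNA as well.

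The edgeR step was tested on simulated counts with the same 200 changed genes, chosen above a floor of mean CPM, in each of 10 draws. At the fitted dispersion, over a mean of 14310 genes, it recovered 4.8% of genes changed by a log2 of 1, 68.6% at 2, 93.2% at 3 and 99.2% at 4, with 7.45% of calls false. At 0.1 times that dispersion it recovered 97.4% at a log2 of 1, over a mean of 14426 genes, with 6.89% of calls false.

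Alternatives were DESeq2 size factors, the DESeq2 1.42.0 test, no filter on low counts, the library number series as a covariate, stricter and absent cell filters, doublets kept, a Leiden resolution of 1.0, thinning to the lowest library total, other thinning and thresholds for the states, and each library left out in turn. Fits on keratin-only cells and on cells below the cycling threshold were added after the data were seen. Intervals and floors of 3 UMIs cover counting error only.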

Results

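Single-cell transcript counts were measured in 6 bladder tumour libraries from mice that carry a Cre-dependent Cas9 and eGFP allele. In 3 libraries (basal-induced) tamoxifen-activated Cre was under the control of keratin 5 (CK5), a gene of basal cells. In the other 3 (luminal-induced) it was under the control of uroplakin 2, a gene of the intermediate and umbrella layers. Tamoxifen was given at 7 weeks of age, plasmids with guides against Pten and Trp53 were electroporated into the bladder 2 weeks later. GFP-marked lesions were excised at 13 months. The comparison addresses how tumours started in basal cells differ from tumours started in intermediate or umbrella cells. The Cre mouse line differs between the groups in the same libraries as the induced cell type. A difference of line or strain background therefore cannot be told apart from it in any class of cells. The basal-induced libraries held 40463984, 43244480 and 28837382 UMIs over 3152, 3243 and 1911 barcodes. The luminal-induced libraries held 10856902, 23800792 and 44288248 UMIs over 1737, 1744 and 4116 barcodes. After filtering, 14948 cells remained, of which 11561 were urothelial-like.

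Most cells of each tumour were urothelial-like, at 80.1% ± 8.69 (SD, n = 3) of the cells in basal-induced and 71.3% ± 11.3 in luminal-induced libraries. Endothelial-like cells, which line vessels, made up 1.71%, 1.84% and 2.25% of the cells of the basal-induced libraries and 7.88%, 6.14% and 3.15% of those of the luminal-induced libraries. Macrophage-like cells averaged 2.30% ± 1.11 against 0.775% ± 0.593, and T or NK-like cells 0.409% ± 0.453 against 1.24% ± 0.979. Fibroblast-like cells averaged 8.53% ± 5.90 against 11.2% ± 9.51, and smooth muscle or pericyte-like cells 2.51% ± 1.32 against 2.17% ± 0.996. Cells nearest to the dendritic markers (dendritic-like) averaged 1.02% ± 1.16 against 0.912% ± 0.479. Their identity is uncertain, since their cluster had 0 of the dendritic markers among its 10 leading genes, which included class II genes and the mast cell proteases Mcpt1 and Mcpt2. No share passed a threshold of 0.05, which 3 libraries against 3 cannot reach. The smallest exact permutation p was 0.1, for the endothelial-like share, and the lowest adjusted value over the 7 classes was 0.7. Within the lower-numbered library series the endothelial-like share was 1.78% in basal-induced against 3.15% in luminal-induced libraries, and within the higher-numbered series 2.25% against 7.01%. The urothelial-like share was 85.1% against 75.6% and 70.1% against 69.1%. The macrophage-like share was 2.85% against 0.416% and 1.21% against 0.954%, and the T or NK-like share 0.148% against 0.650% and 0.932% against 1.54%. The directions of the fibroblast-like (5.12% against 13.8%, then 15.3% against 9.87%), smooth muscle or pericyte-like (3.16% against 1.17%, then 1.21% against 2.67%) and dendritic-like shares (0.347% against 0.572%, then 2.36% against 1.08%) did not hold in both series.

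With every cell thinned to 2000 UMIs, urothelial-like cells with basal keratins and no uroplakin were on average the largest of 4 states in basal-induced tumours. Cells with uroplakins and no basal keratin were the largest in luminal-induced tumours, except in luminal-induced 1. Cells with RNA of Krt5 or Krt14, the keratins of the basal layer, and none of Upk1a, Upk2 or Upk3a, plaque proteins of the umbrella cell surface, made up 41.5%, 72.0% and 66.1% of urothelial-like cells in basal-induced libraries and 42.0%, 8.65% and 10.4% in luminal-induced libraries (exact permutation p = 0.2). Cells with uroplakin RNA alone made up 14.3% ± 11.03 against 39.3% ± 11.4 (mean ± SD, n = 3, exact permutation p = 0.1). Cells with both made up 20.9% ± 6.13 against 33.9% ± 8.15 (exact permutation p = 0.2), and cells with neither 4.97% ± 0.528 against 6.55% ± 1.39 (exact permutation p = 0.2). Cells in division, those with at least 2 UMIs over 20 genes of the G2 and M phases, made up 7.11%, 13.4% and 9.61% of basal-induced and 1.58%, 0.208% and 0.379% of luminal-induced urothelial-like cells. This gap was larger than the spread between libraries (exact permutation p = 0.1). All 5 adjusted values were 0.2. Among keratin-only cells alone the cycling share was 15.1% ± 1.22 against 1.69% ± 1.90 (n = 3, exact permutation p = 0.1), with 0 of 83 such cells in luminal-induced 2, which allows up to 3.61%.

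Every cell was thinned to 2000 UMIs for these shares, since urothelial-like cells held median UMIs between 6370.5 and 16336.5 by library. In endothelial-like cells, which should lack both gene sets, 0% to 15.3% held a keratin UMI and 0% to 18.0% a uroplakin UMI at the same thinned depth, from library medians of 2618 to 7755 UMIs. Both highest values came from luminal-induced 1. Cells with many epithelial UMIs had been left out of this class, so these values can understate the background. In urothelial-like cells the ranges were 46.9% to 92.0% and 24.0% to 83.9%. Without thinning, keratin-only cells averaged 36.5% against 12.7%, uroplakin-only cells 4.23% against 10.8%, and cells with both 59.1% against 75.9%, so cells with both were then the largest state in each group. Cells with neither averaged 0.194% against 0.589%, and cycling cells 23.9% against 4.59%. Within the lower-numbered series keratin-only cells made up 56.7% in basal-induced against 10.4% in luminal-induced libraries, and within the higher-numbered series 66.1% against 25.3%. The same comparisons gave 14.5% against 46.2% and 13.8% against 35.8% for uroplakin-only cells, and 23.7% against 35.7% and 15.2% against 32.9% for cells with both. They gave 5.04% against 7.67% and 4.84% against 5.98% for cells with neither, and 10.3% against 0.379% and 9.61% against 0.892% for cycling cells. Luminal-induced 1, whose keratin-only share was near that of basal-induced 1, had the lowest depth of the 6 libraries.

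**Figure D1:**
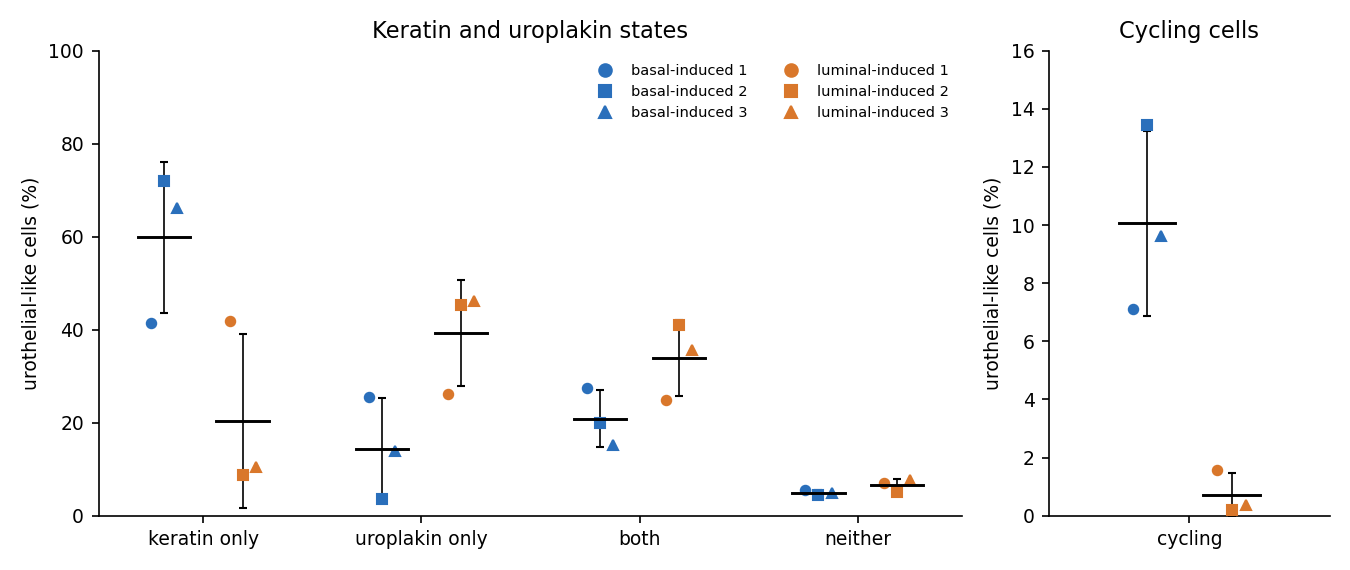
Share of urothelial-like cells (%) in each keratin and uroplakin state and of cycling cells, 1 point per library, with the mean (black bar) and SD (error bar) of 3 libraries per group. Cycling cells lie between 7.11% and 13.4% in basal-induced and between 0.208% and 1.58% in luminal-induced libraries.

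The guide targets Pten and Trp53, tumour suppressors, were counted in urothelial-like cells of every library. Pten was at 137, 157 and 174 CPM in basal-induced and 121, 98.4 and 124 CPM in luminal-induced libraries (log2 fold change 0.45 ± 0.18 SE, adjusted p = 0.174). Trp53 differed by 0.35 ± 0.25 (adjusted p = 0.390). Counts from the 3' ends of transcripts do not show small insertions or deletions at a guide site, so they check neither edit. Urothelial-like cells may therefore include unedited cells excised with the lesion. Krt5, whose promoter drove Cre in the basal-induced mice, was at 1333 ± 220 CPM against 511 ± 263 (log2 fold change 1.38 ± 0.37 SE, adjusted p = 0.0954). Upk2, the corresponding gene of the luminal-induced mice, was at 64.0 ± 35.3 CPM against 199 ± 80.0 (log2 fold change −1.64 ± 0.54 SE, adjusted p = 0.129). Neither passed the threshold, although the libraries of the groups did not overlap for either gene. No feature named for eGFP or Cas9 was among the features analysed. A feature named TOMATO, a red fluorescent protein that the labels do not mention, was at 84.4 ± 42.6 CPM against 21.7 ± 3.94 (log2 fold change 1.96 ± 0.42 SE, adjusted p = 0.0735). A feature named YFP, of which it is not known whether it counts the eGFP of the allele, was at 10.8, 6.24 and 0 CPM in basal-induced and 0, 1.13 and 21.7 CPM in luminal-induced libraries.

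In urothelial-like cells of basal-induced tumours, genes of DNA replication and mitosis rose, together with an adhesion gene of basal epithelium and a matrix gene. A differing share of unedited cells was not separated from a change within tumour cells. Pclaf, a partner of the replication clamp PCNA, was at 49.6 ± 17.8 CPM (SD, n = 3) against 1.47 ± 0.126 CPM in luminal-induced libraries, a log2 fold change of 5.06 ± 0.34 (SE; adjusted p = 0.00727). The mitotic genes Mad2l1 (spindle checkpoint), Birc5 (survivin, of the chromosomal passenger complex) and Cdca3 (mitotic entry) rose by a log2 of 4.18 ± 0.53, 3.89 ± 0.48 and 3.60 ± 0.57 (adjusted p = 0.0410, 0.0410 and 0.0464). Cdh3, the P-cadherin of basal epithelial cells, rose by 3.31 ± 0.52 (adjusted p = 0.0449), and Fn1, the matrix glycoprotein fibronectin, by 4.91 ± 0.75 (adjusted p = 0.0430). The lists of stromal and immune markers did not pass (camera adjusted p = 0.952 and 0.903). Cells past thresholds for some of these markers had been left out beforehand, so this does not exclude stromal RNA as a source of Fn1. Sncg (gamma-synuclein), at 74.2 ± 20.5 against 3.39 ± 1.86 CPM, rose by 4.49 ± 0.44 (adjusted p = 0.0263). Tspan1, a tetraspanin, rose by 4.55 ± 0.65 and Car2, a carbonic anhydrase, by 3.20 ± 0.43 (adjusted p = 0.0410 for each). Crisp1, a secreted protein known from the epididymis, showed the largest named change, 8.78 ± 1.17 (adjusted p = 0.0410), from 5890 UMIs in basal-induced and 6 in luminal-induced libraries. It lies on a stretch of chromosome 17 where 5 genes were counted outside the urothelium in basal-induced libraries only or nearly so.

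Fewer genes fell in basal-induced urothelial-like cells. Stard13, a Rho GTPase activating protein, fell from 125 ± 26.6 CPM in luminal-induced to 26.3 ± 10.6 CPM in basal-induced libraries (log2 fold change −2.25 ± 0.33 SE, adjusted p = 0.0410). The circadian repressor Cry2 fell by a log2 of −1.26 ± 0.20 (adjusted p = 0.0464). Rnaset2b, a lysosomal ribonuclease, fell by −1.63 ± 0.24 (adjusted p = 0.0410) while its near-identical copy Rnaset2a did not pass (0.00 ± 0.26, adjusted p = 0.999). Hmga1, a chromatin protein, fell by −1.19 ± 0.17 (adjusted p = 0.0410). Hmga1 lies on chromosome 17, 250 annotation entries from the class II gene H2-Ea, which was counted in basal-induced libraries only. A difference of strain on this stretch cannot be told apart from the induced cell type. The near-identical Hmga1b was counted at 20.6 ± 1.53 CPM in basal-induced against 0.166 ± 0.145 CPM in luminal-induced libraries. In both pairs reads can be split between the copies, so these values are uncertain. The next 6 genes by p in this direction did not pass: Myo1e (−1.04, adjusted p = 0.0558), Pnpla8 (−1.03, 0.0595), Nedd4l (−0.97, 0.0619), Snhg4 (−0.91, 0.0619), Ppm1h (−1.74, 0.0619) and Vti1a (−0.79, 0.0629).

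Of 14597 genes tested in urothelial-like cells, 150 were higher and 21 lower in basal-induced tumours, including 7 and 11 predicted genes; 54 and 4 met the rule for names. None of the 171 called genes overlapped between the groups' libraries, and neither did 33.7% of all genes tested, where chance gives 10%. The groups drew many of these cells from different clusters. A cluster led by S100g, Col17a1 and Krt14 held 2790 basal-induced cells (890 and 1900 from basal-induced 1 and 2) and 0 luminal-induced cells. A cluster led by Cxcl3 and Krt13 held 818 cells of basal-induced 3, and a cluster led by Trf and Upk3a held 489 basal-induced cells, all of basal-induced 1, and 2548 luminal-induced cells. A cluster led by Cyp2f2 and Cxcl5 was shared, with 464, 6 and 437 cells of the basal-induced and 699, 5 and 3 of the luminal-induced libraries. The calls depended on single libraries. Without basal-induced 1, luminal-induced 2 or luminal-induced 3, edgeR called 0 genes (1615, 1281 and 1566 higher and 1325, 958 and 1392 lower at an unadjusted p under 0.05). Without basal-induced 2 it called 3 higher and 1 lower, and without basal-induced 3 or luminal-induced 1 it called 1419 and 607 higher and 437 and 103 lower. With the library number series as a covariate 4 genes were higher and 1 lower, and DESeq2 called 1284 higher and 709 lower, the 171 among them. In fits chosen after the results were seen, cells below the cycling threshold gave 16 higher and 2 lower, all among the 171, and keratin-only cells gave 41 and 19, with 42 among the 171. Of 29 named genes that passed, 21 lost their call below the cycling threshold and 12 in keratin-only cells. Below the cycling threshold the fold change of Cdh3 was 3.26 ± 0.52 (adjusted p = 0.0789) and that of Fn1 4.86 ± 0.72 (adjusted p = 0.0750). Their unadjusted p stayed near that over all urothelial-like cells (0.000426 after 0.000418, and 0.000283 after 0.000341), so these calls ended in the adjustment. The fold change of Aurka fell from 3.61 ± 0.55 to 1.27 ± 0.50 (adjusted p = 0.198), its cells having been left out by the threshold, and Sncg kept its call at 4.23 ± 0.43 (adjusted p = 0.0338).

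**Figure D2:**
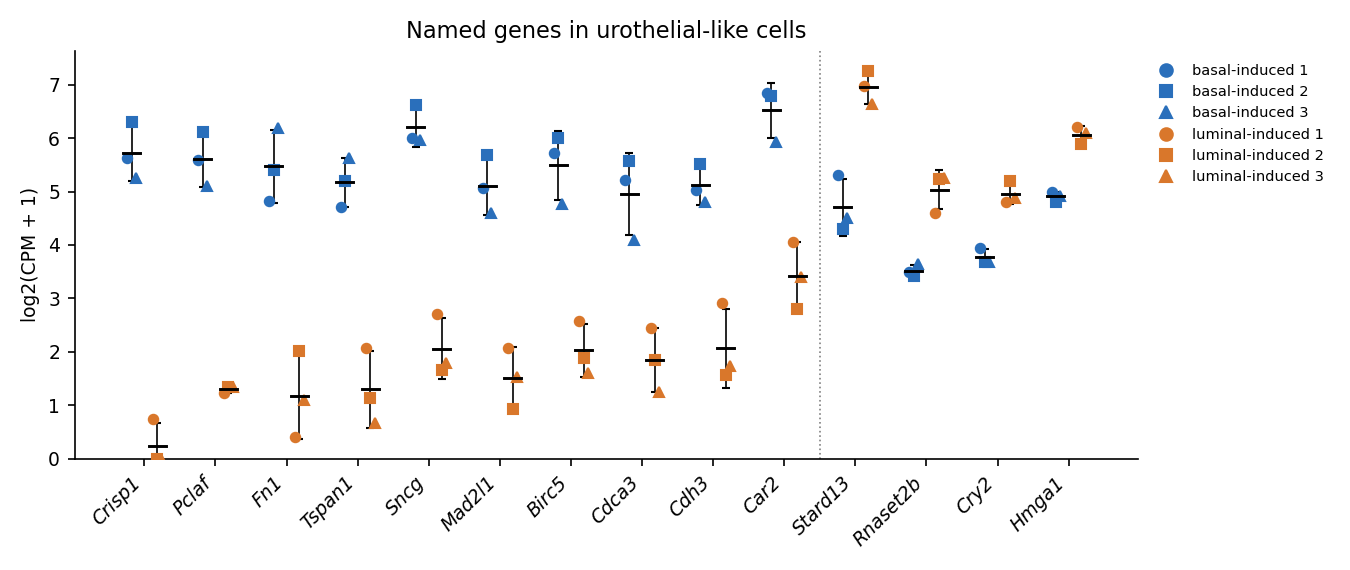
CPM of the named genes in urothelial-like cells, as log2(CPM + 1), 1 point per library, with the mean (black bar) and SD (error bar) of 3 libraries per group; genes to the right of the dotted line were lower in basal-induced tumours. The basal-induced and luminal-induced libraries do not overlap for any of these genes, which the rule for named genes required.

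Genes of the cell cycle rose as groups. Of 10 splits of the libraries into groups of 3, 8, the real one among them, gave 10 or more lists past camera at the preset correlation. A pass by camera alone therefore does not tie a list to the induced cell type. All 20 measured genes of the G2M list had a positive fold change, with a median log2 of 3.40 (camera adjusted p = 1.56e-24; adjusted p = 0.399 with an estimated correlation). Of these, 5 rose over all genes, 0 fell and 15 did not pass, and 20 rose adjusted over the list alone. Examples are Aurkb (5.21 ± 0.36 SE, adjusted p = 0.00727), Cdk1 (3.99 ± 0.59, adjusted p = 0.0410) and Aurka (3.61 ± 0.55, adjusted p = 0.0423), kinases of mitosis. Tpx2, a spindle protein, rose by 2.99 ± 0.50 (adjusted p = 0.0498). Of 20 genes of the S phase list, with a median of 2.09 (camera adjusted p = 9.59e-24; adjusted p = 0.399 with an estimated correlation), 11 rose, 0 fell and 9 did not pass, and 19 rose adjusted over the list alone. Among them were Uhrf1 (4.20 ± 0.41, adjusted p = 0.0263), which maintains DNA methylation at replication, and Dtl (5.70 ± 0.63, adjusted p = 0.0296), a ubiquitin ligase adaptor with 5 UMIs in luminal-induced libraries. Others were the helicase subunits Mcm5 (2.98 ± 0.30, adjusted p = 0.0271) and Mcm3 (2.24 ± 0.26, adjusted p = 0.0386), and Rrm1 (1.62 ± 0.21, adjusted p = 0.0410) of ribonucleotide reductase.

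The glycolysis list passed by camera at the preset correlation, with few genes past the threshold. Of 16 measured, 14 had a positive fold change, 3 rose over all genes, 0 fell and 13 did not pass, and 10 rose adjusted over the list alone (median 1.17, camera adjusted p = 7.68e-07; adjusted p = 0.399 with an estimated correlation). The 3 were Ldha (lactate dehydrogenase, 1.46 ± 0.21), Pgk1 (phosphoglycerate kinase, 1.55 ± 0.23) and Eno1 (enolase, 1.27 ± 0.18), each with an adjusted p of 0.0410. Pgam1, the mutase of the same pathway, was at 1.64 (adjusted p = 0.0619). The hypoxia list had a median of 1.11 over 14 genes (camera adjusted p = 0.00292; adjusted p = 0.683 with an estimated correlation), with 0 genes past the threshold over all genes and 5 adjusted over the list alone. Its members with the smallest p were Ero1a, an endoplasmic reticulum oxidase (1.01, adjusted p = 0.0679), Adm, the vasodilator adrenomedullin (2.31, adjusted p = 0.0700), and Vegfa, the endothelial growth factor (1.17, adjusted p = 0.0784).

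The inflammatory and squamous lists passed by camera at the preset correlation, without a member past the threshold over all genes. The median over 22 cytokine genes was 1.43 (camera adjusted p = 0.00222; adjusted p = 0.683 with an estimated correlation), with 0 genes past the threshold over all genes and 0 adjusted over the list alone. Its members included the neutrophil chemokine Cxcl3, at 29.98, 29.97 and 689 CPM in basal-induced and 1.88, 2.12 and 0.417 CPM in luminal-induced libraries (log2 fold change 7.49 ± 1.69, adjusted p = 0.0782). The growth factor Csf2 was at 3.50 (adjusted p = 0.104) and the cytokine Il18 at 1.62 (adjusted p = 0.125). Of 20 squamous genes (median 1.37, camera adjusted p = 0.00729; adjusted p = 0.683 with an estimated correlation) 0 passed over all genes and 4 rose adjusted over the list alone. Among them, Sprr1b, a cornified envelope protein with 344 UMIs against 1 (ratio 222, 95% counting interval 39.6 to 8809), had an adjusted p of 0.0665. Dmkn (dermokine) was at 2.07 (adjusted p = 0.0839) and Sprr2a3 at 1.55 (adjusted p = 0.0962). Sprr2a3 has near-identical copies, of which Sprr2a1 (2.13 ± 0.28, adjusted p = 0.0410) and Sprr2a2 (2.27 ± 0.27, adjusted p = 0.0386) rose. Both lists lost their call without basal-induced 3 (adjusted p = 0.0822 and 0.0883), where values over the 6 fits that leave out a library reached down to 2.88e-11 and 4.27e-11.

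Luminal differentiation genes fell as a list only by camera at the preset correlation. The median over 22 genes was −0.90 (camera adjusted p = 0.000462; adjusted p = 0.683 with an estimated correlation), with 0 genes past the threshold over all genes and 1, Krt20, lower adjusted over the list alone. Krt20, a keratin of umbrella cells, was at −0.96 (adjusted p = 0.0700), and the uroplakin Upk3b at −1.59 (adjusted p = 0.0919). The simple epithelial keratins Krt18 and Krt8 were at −1.60 and −1.15 (adjusted p = 0.105 and 0.118). The list of basal keratins and adhesion genes, with a median of 0.60 over 16 genes, did not pass (camera adjusted p = 0.0523), and 0 of its genes passed over all genes and 1 adjusted over the list alone. It passed without basal-induced 1 (adjusted p = 0.0108), basal-induced 2 (0.0184) or luminal-induced 1 (3.61e-06), and the highest value over the 6 fits was 0.424. Its laminin chains Lamc2 and Lama3, of the basement membrane, were at 1.12 and 1.07 (adjusted p = 0.0742 and 0.191).

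Ribosomal, sterol and MHC class II genes also fell as lists only by camera at the preset correlation. All 20 ribosomal protein genes had a negative fold change (median −0.62, camera adjusted p = 1.82e-06; adjusted p = 0.683 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. Rpl15, Rps6 and Rpl8 were at −0.76, −0.92 and −0.84 (adjusted p = 0.0908, 0.0955 and 0.103). The mitochondrially encoded list, which moves with RNA quality, went the other way without passing (12 of 13 genes positive, median 0.33, camera adjusted p = 0.0777). It passed without basal-induced 1 (adjusted p = 0.0319), basal-induced 2 (0.0241) or luminal-induced 3 (0.0264), and the highest value over the 6 fits was 0.424. Of 20 cholesterol and lipid genes (median −0.43, camera adjusted p = 0.00729; adjusted p = 0.683 with an estimated correlation) 0 passed over all genes and 1 rose and 1 fell adjusted over the list alone. The sterol reductase Dhcr7 had a positive fold change (adjusted p = 0.0641). The fatty acid synthase Fasn was at −0.95 (adjusted p = 0.0817) and Insig1, which holds back sterol synthesis, at −0.84 (adjusted p = 0.112). The call was lost without luminal-induced 3 (adjusted p = 0.119; lowest of the 6 fits 0.00179). Of 6 MHC class II genes (median −0.77, camera adjusted p = 0.0301; adjusted p = 0.683 with an estimated correlation) 0 passed over all genes and 2 fell adjusted over the list alone. H2-Eb1, the beta chain of an antigen-presenting dimer, was at −2.73 (adjusted p = 0.0655) and H2-DMb1, a peptide loader, at −2.15 (adjusted p = 0.0787). Before TMM scaling H2-Eb1 was at 4.69, 1.21 and 4.75 CPM against 26.0, 18.3 and 23.3 CPM in urothelial-like cells. Outside the urothelium it was at 608, 541 and 370 CPM against 1408, 803 and 489 CPM, and in macrophage-like cells at 2419, 1972 and 2775 CPM against 12349, 11746 and 10585 CPM. Outside the urothelium as a whole the groups overlapped. H2-Aa, near H2-Eb1 outside the urothelium in luminal-induced 3 (494 CPM), was at 2.41 CPM in the urothelial-like cells of that library. Cd74, the invariant chain, was at −0.71 (adjusted p = 0.581) and H2-Ab1 at 0.68 (adjusted p = 0.654). This call was lost without basal-induced 1 (adjusted p = 0.0618) and luminal-induced 1 (adjusted p = 0.0943), with a lowest value of 0.0191 over the 6 fits. H2-Ea, the partner chain of H2-Eb1, was counted in cells outside the urothelium in basal-induced libraries only. Both genes lie on chromosome 17. A difference of strain there was not tested and cannot be told apart from the induced cell type.

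Of 31 lists tested, 6 rose and 4 fell by camera at the preset correlation, and 0 passed with an estimated correlation (3 lists had an unadjusted p under 0.05). Fry called 3 lists, G2M, S phase and glycolysis (adjusted p = 0.0362 for each). The p53 target list, whose regulator was a guide target, did not pass (median −0.05, mean 0.39, test direction up, camera adjusted p = 0.851), and 0 of its 23 genes passed over all genes or adjusted over the list alone. The epithelial-to-mesenchymal list did not pass either (median 0.60, camera adjusted p = 0.113), except without luminal-induced 2 (adjusted p = 0.0126; highest of the 6 fits 0.186). Of its 16 genes 1, Fn1, rose over all genes and 4 adjusted over the list alone. S100a4, a marker of motile cells, was at 1.93 (adjusted p = 0.0619). Slc7a11, the cystine transporter, rose by 2.90 ± 0.38 (adjusted p = 0.0410) in a list of NRF2 targets with a median of −0.62 that did not pass (camera adjusted p = 0.152), except without basal-induced 1 (adjusted p = 0.0359; highest of the 6 fits 0.372). Gpx2 and Nqo1, enzymes against oxidants, were at 2.16 and −1.36 (adjusted p = 0.0593 and 0.0711), and 3 of 18 genes rose and 4 fell adjusted over the list alone. Etv4, a transcription factor downstream of receptor tyrosine kinases, rose by 4.13 ± 0.60 (adjusted p = 0.0410) from 7 UMIs in luminal-induced and 237 in basal-induced libraries. Its list did not pass (camera adjusted p = 0.380), with 1 of 20 genes up over all genes and 3 adjusted over the list alone. The stromal marker list had a negative median (−0.05) with the test direction up, the immune marker list likewise (−0.18), and the list of dissociation stress genes a positive median (0.13) with the test direction down (adjusted p = 0.999).

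**Figure D3:**
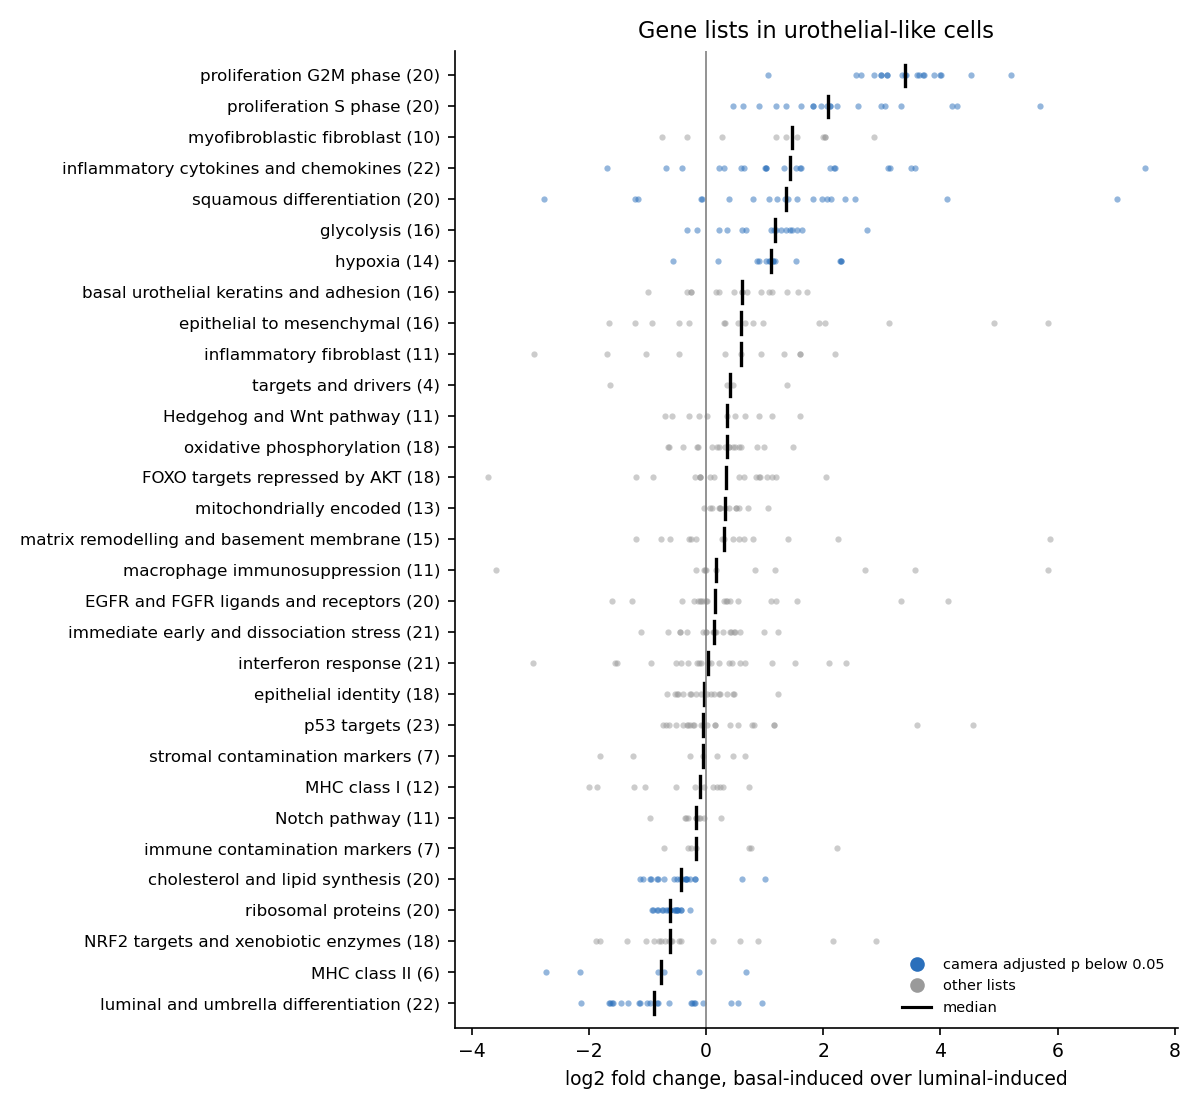
Log2 fold change, basal-induced over luminal-induced, of each measured member (dots) and the median (tick) of the 31 gene lists in urothelial-like cells; lists in blue had a camera adjusted p under 0.05 at the preset correlation. The number of measured genes is in brackets, and the G2M list has the highest median, 3.40.

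Fibroblast-like cells differed between the tumours in 177 genes, and no gene list was tested in them. Inhba, the activin A subunit, was at 203, 328 and 903 CPM in basal-induced libraries and 0.741 and 0 CPM in luminal-induced libraries, from 2349 UMIs against 2 (log2 fold change 10.02 ± 1.06 SE, adjusted p = 0.00858; ratio of pooled counts 1456, 95% counting interval 403 to 12027). Col6a5, a collagen VI chain, rose by 8.76 ± 0.64 (adjusted p = 0.00213; 468 UMIs against 1, ratio 580.02, interval 104 to 22958). Serpina3m, a protease inhibitor of a family of close copies, rose by 6.05 ± 0.81 (adjusted p = 0.0147; 100 UMIs against 2, ratio 62.0, interval 16.7 to 519). The adhesion molecule Chl1 rose by 6.34 ± 0.54 (adjusted p = 0.00405) and the metalloreductase Steap4 by 6.14 ± 0.92 (adjusted p = 0.0200). Gdpd3, a lysophospholipase, fell, with 3 UMIs in basal-induced and 244 in luminal-induced libraries (log2 fold change −5.82 ± 0.60, adjusted p = 0.00858; ratio 65.6 towards luminal-induced, interval 22.2 to 320.4). Over all cells outside the urothelium Gdpd3 was at 0.884, 2.47 and 1.08 CPM in basal-induced and 302, 77.0 and 53.5 CPM in luminal-induced libraries. In urothelial-like cells the groups overlapped. The drop was thus not particular to fibroblast-like cells. A difference of line or strain cannot be told apart from the induced cell type. Nog, the BMP antagonist noggin, fell by −3.33 ± 0.58 (adjusted p = 0.0334) and the small GTPase Arl4d by −3.35 ± 0.49 (adjusted p = 0.0192). Dmkn, an epidermal secreted protein, fell by −3.65 ± 0.72 (adjusted p = 0.0447) and the tubulin regulator Stmn2 by −3.42 ± 0.69 (adjusted p = 0.0492).

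In all, 128 genes were higher and 49 lower of 11326 tested, over 3 basal-induced and 2 luminal-induced libraries, since luminal-induced 1 held 10 fibroblast-like cells. Of these, 104 and 35 met the rule for names. All 177 called genes were without overlap, as were 28.3% of the genes tested, where chance gives 20%. Different clusters held these cells. A cluster with Ibsp, Wif1 and Inhba among its leading genes held 247 basal-induced and 10 luminal-induced cells, and a cluster led by Ereg and Inhba 274 and 0 (271 from basal-induced 3). Clusters led by Car3 held 59 and 382, 6 and 122, and 2 and 230. Counts without basal-induced 2 were 15 higher and 2 lower, and without luminal-induced 2 they were 6 and 5. Without luminal-induced 3 they were 51 and 45, and without basal-induced 3 they were 130 and 25; fits with 1 luminal-induced library assume that it varies like the others. Without a filter on low counts 627 were higher and 286 lower, DESeq2 called 290 and 84, and the series covariate gave 187 and 52.

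**Figure D4:**
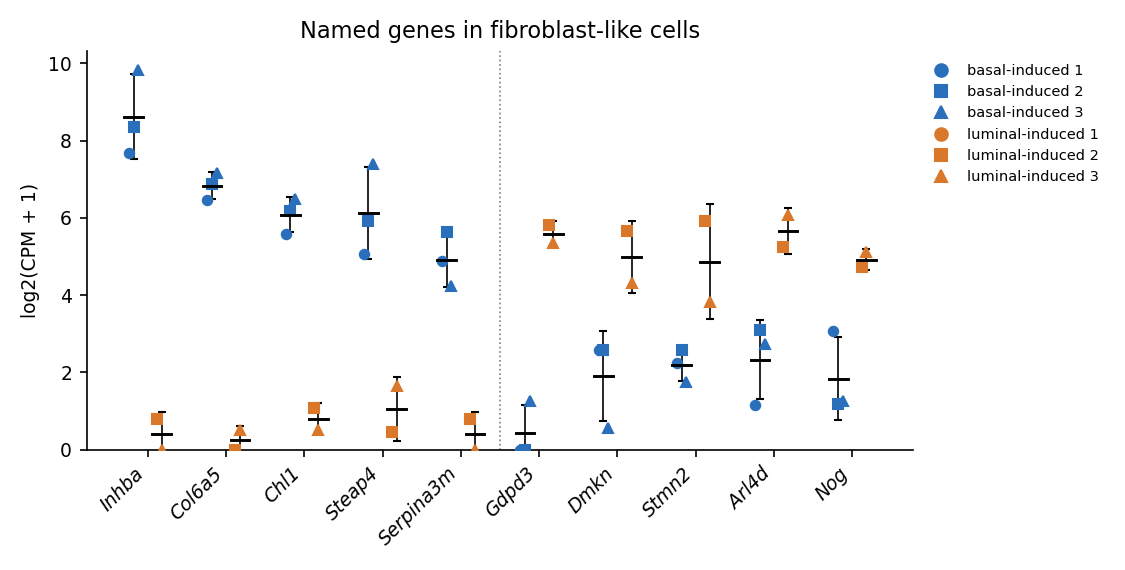
CPM of the named genes in fibroblast-like cells, as log2(CPM + 1), 1 point per library for 3 basal-induced and 2 luminal-induced libraries, with the mean (black bar) and SD (error bar). Genes to the right of the dotted line were lower in basal-induced tumours, and no gene overlaps between groups, which the rule for named genes required.

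Over all kept cells, a comparison that includes the mix of classes, 9 genes were higher and 2 lower of 16172 tested. Without basal-induced 1, basal-induced 2, luminal-induced 2 or luminal-induced 3, edgeR called 0 higher (1469, 1166, 1294 and 1488 at an unadjusted p under 0.05) and 1 lower. Without basal-induced 3 it called 854 and 129, and without luminal-induced 1 it called 119 and 6. DESeq2 called 1004 higher and 534 lower. Macrophage-like cells reached 20 cells in 1 luminal-induced library and T or NK-like cells in 0 basal-induced libraries, so neither class was tested.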

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

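All tests in this part were chosen after the results were seen. A set of 15 genes held at least 3 UMIs outside the urothelium in every library of one group and at most 3 in all libraries of the other. The rule also asked for CPM outside the urothelium more than 5-fold apart between the groups' libraries. It further asked for no overlap between the groups in urothelial-like cells, so that separation was set by the choice. Among them, H2-Ea, a class II chain that several common laboratory strains do not express, drew attention as a signal outside the urothelial comparison, with 318 UMIs in basal-induced and 0 in luminal-induced libraries (33.5 ± 19.3 CPM, SD, n = 3, at least 100.1-fold higher against a floor of 3 UMIs over the group). The called genes other than Crisp1 were found outside at 15.99% or more of their urothelial CPM, where the highest of 9 urothelial markers reached 4.59%. The set was chosen for UMIs outside, so members low in urothelial-like cells were bound to exceed that value. The comparison therefore does not decide on free RNA from urothelial-like cells for the called genes as a set. Free RNA is argued against for BC023719, with 36, 35 and 34 UMIs outside (82.0%) where the rule asked for 3. Crisp1, at 4.04%, lay within the range of the markers, so free RNA could account for its UMIs there. A strain difference on 1 stretch of a chromosome may account for part of the set: 5 genes (H2-Ea, Gm8801, A930015D03Rik, BC023719 and Crisp1, all seen in basal-induced libraries) lie within 1000 neighbouring annotation entries on chromosome 17, against a median of 2 and a highest value of 6 in 10000 random sets (permutation p = 0.00170). For Hmga1 and Hmga1b, reads shared between the copies and a real difference cannot be told apart, because the summed CPM differed by −13.5 (basal minus luminal) with a spread of 8.01 between libraries; the induced cell type, which separates the same libraries, also stays open for the whole set as untested.

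Cycling urothelial-like cells made up 7.11% to 13.4% of basal-induced and 0.208% to 1.58% of luminal-induced libraries. Free RNA from cycling cells would reach every class of a library. At most 1.26% of the fibroblast-like cells of a basal-induced library passed the same threshold. Cells with many epithelial UMIs had been left out of that class, so it can understate free RNA. Of endothelial-like cells 5.88%, 17.5% and 12.2% passed, and of smooth muscle or pericyte-like cells up to 27.7%, and what raised these was not tested. The values therefore do not decide on free RNA. A larger share of keratin-only cells is argued against as the whole cause, since among keratin-only cells the lowest basal-induced library still lay 10.1 percentage points above the highest luminal-induced library. The library number series is argued against, since within both series the groups stayed at least 6.74 points apart. A difference tied to the induced cell type is left as a hypothesis, found and tested on the same libraries.

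The YFP feature, which the labels do not mention, held 390, 242 and 0 UMIs in the urothelial-like cells of the basal-induced and 0, 20 and 786 of the luminal-induced libraries. Depth is argued against, since 3 UMIs stand for at most 0.333 CPM in the higher-numbered libraries, below the 6.24 CPM of the lowest lower-numbered library. The library number series could mark the difference: every lower-numbered library lay at least 5.12 CPM above every higher-numbered library (exact permutation p = 0.1, the smallest possible, against 0.9 for the induced cell type). No eGFP feature was found although the mice carry a Cas9 and eGFP allele, so whether the YFP counts stand for eGFP is open. What the number stands for is not stated, and no biological explanation was tested.

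Sncg drew attention because its group effect differed between urothelial-like and endothelial-like cells by a log2 of 5.57 in a separate limma fit of per-library differences (adjusted p = 0.0147, the 1 gene of 5410 tested to pass), where the edgeR fits of each class gave 4.49 and −1.01 (adjusted p = 0.0263 and 0.352). Of the cells left unnamed, cluster 7 held 144 cells with Cnn1, Des, Actg2, Myh11, Vip and Penk among its leading genes, 104 of them in luminal-induced 2. Cluster 10 held 17 cells led by the melanocyte genes Dct, Tyrp1, Pmel and Mlana, 5 in basal-induced 1 and 12 in basal-induced 2. Cluster 17 held 35 cells with the B and plasma cell genes Jchain, Mzb1 and Ms4a1, 27 of them in basal-induced 3.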

How the results depend on the processing

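The endothelial-like test with its settings, the fits on keratin-only cells and on cells below the cycling threshold, the doublet rule and the splits of the libraries were chosen after the results were seen. Counts are given as higher and lower in basal-induced libraries, and the cause of a change was not tested except where fewer cells or libraries entered a fit. Against 150 and 21 in urothelial-like cells, the DESeq2 test called 1284 and 709, no filter on low counts gave 382 and 73, the series covariate 4 and 1, keratin-only cells 41 and 19, and cells below the cycling threshold 16 and 2; the stricter cell filter gave 36 lower. Of the 171 genes, 171 were called without basal-induced 3, 165 without luminal-induced 1, 127 when thinned to the lowest library total, 42 in keratin-only cells and 18 in cells below the cycling threshold. With each library left out, the counts ran from 0 to 1419 and from 0 to 437; edgeR called 0 without basal-induced 1, luminal-induced 2 or luminal-induced 3 (1615, 1281 and 1566 higher and 1325, 958 and 1392 lower at an unadjusted p under 0.05), 3 and 1 without basal-induced 2, 1419 and 437 without basal-induced 3, and 607 and 103 without luminal-induced 1. In fibroblast-like cells (128 and 49), DESeq2 called 290 and 84, no filter on low counts 627 and 286 and no cell filter 69 and 25, while thinning gave 85 and the stricter cell filter 83 higher. Leaving out a library gave 6 to 172 and 2 to 53, with 15 and 2 without basal-induced 2, 25 lower without basal-induced 3, 6 and 5 without luminal-induced 2 and 51 higher without luminal-induced 3. Over all cells (9 and 2), DESeq2 called 1004 and 534, no filter 192 and 26 and the covariate 2 and 1; leaving out a library gave 0 to 854 and 1 to 129, with 0 and 1 without basal-induced 1, basal-induced 2, luminal-induced 2 or luminal-induced 3 (1469, 1166, 1294 and 1488 higher at an unadjusted p under 0.05), 854 and 129 without basal-induced 3, and 119 and 6 without luminal-induced 1. In endothelial-like cells (3 and 2), DESeq2 called 83 and 58, no filter 278 and 236 and the stricter cell filter 20 and 20, while edgeR with the covariate called 0 and 0 (338 and 362 unadjusted); 1 was lower when thinned, with no cell filter, with doublets kept and at a Leiden resolution of 1.0, and leaving out a library gave 0 to 483 and 0 to 482. Of 10 gene lists past camera, 0 passed with an estimated correlation and 3 with fry.

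The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. In urothelial-like cells the real split gave 171 genes and the highest other split 0, so 1 of 10 splits gave as many; over all cells these were 11 and 0 (1 of 10), and in endothelial-like cells 5 and 0 (1 of 10). For gene lists, camera called 10 in the real split and at most 16 in another, with 8 of 10 splits giving as many, and fry called 3 and at most 2 (1 of 10). The split that follows the library number series gave 13 lists by camera, more than the real one, 1 by fry and 0 genes.

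Differences in class shares (basal minus luminal, percentage points) turned sign in a few settings. The dendritic-like difference of 0.104 became −0.00540 with doublets kept and −0.00524 at a Leiden resolution of 1.0, and ran from −0.565 to 0.467 with a library left out (−0.565 without basal-induced 3, −0.0656 without luminal-induced 3). The fibroblast-like difference of −2.66 became 0.309 with the stricter cell filter and ran from −7.93 to 1.3003 (without luminal-induced 2). The smooth muscle or pericyte-like difference of 0.340 became −0.580 with no cell filter and −0.661 at a Leiden resolution of 1.0, and ran from −0.325 to 0.993 (−0.325 without basal-induced 2, −0.159 without luminal-induced 3). In all other settings tried, 124 of 134 in all, share differences kept their sign. Of 1351 alternative fits of named genes, 1028 stayed on the same side of the threshold, 242 fell below it, 81 passed newly and 0 changed sign among called values; of 117 for the 13 gene lists named by rule 91, 22, 4 and 0 did. For the other 18 lists, 10 of 162 alternative fits passed newly, in 6 lists, and 0 were lost.

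No paired analysis was possible because the replicate numbers follow the order of deposition and tie no libraries together. The tests of macrophage-like and T or NK-like cells, with their alternatives, were not run for lack of cells, and the T or NK-like share has no value with doublets kept, where no cluster took that name. Luminal-induced 1 held the fewest UMIs, 10856902, and thinning to the lowest library total gave 122 and 14 genes in urothelial-like cells. In simulated data 4.8% of genes changed by a log2 of 1 were recovered at the fitted dispersion and 97.4% at 0.1 times it. The spread between libraries therefore limits small changes for genes above the CPM floor of the simulation. Changed genes of low counts were not simulated and depth was not varied.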

Other observations

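The tests in this part, of endothelial-like genes and of cycling in other classes, were chosen after the results were seen. Endothelial-like and smooth muscle or pericyte-like cells passed the cycling threshold more often in basal-induced libraries. Of endothelial-like cells, 5.88%, 17.5% and 12.2% held at least 2 UMIs of the G2M genes in basal-induced libraries and 1.80%, 1.98% and 2.48% in luminal-induced libraries (exact permutation p = 0.1). Of smooth muscle or pericyte-like cells, 12.2%, 27.7% and 13.6% did against 0%, 3.85% and 2.22% (exact permutation p = 0.1), where 0 of 31 cells in luminal-induced 1 allows up to 9.68%. The groups drew both classes in unlike shares from their clusters, so a change of subtype and a change within a subtype were not separated. Of endothelial-like cells, a cluster with Apln, Esm1 and Plvap held 77 basal-induced (25, 50 and 2 by library) and 5 luminal-induced cells. A cluster with Selp, Sele and Ackr1 held 26 and 193, and clusters led by Cldn5 and by Cdh5 held 19 and 58, and 27 and 89. Of smooth muscle or pericyte-like cells, a cluster with Postn and Cpa1 held 167 and 3 (58, 106 and 3 by basal-induced library), and a cluster with Myh11 and Sncg held 48 and 128. Fibroblast-like cells, thinned alike, stayed at 0.419% ± 0.726 against 0.275% ± 0.327 (SD, n = 3, exact permutation p = 1).

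Of 5581 genes tested in endothelial-like cells, 3 rose and 2 fell in basal-induced libraries, and 20.6% of genes did not overlap between groups, where chance gives 10%. These cells came in unlike shares from shared clusters (77 and 5, 26 and 193, 19 and 58, and 27 and 89 cells of basal-induced and luminal-induced libraries). Basal-induced 3 held 2 cells of the first of these. Col13a1, a transmembrane collagen, was at 179 ± 109 CPM against 7.32 ± 2.87 (log2 fold change 4.61 ± 0.63 SE, adjusted p = 0.0440). Ddah1, which degrades an inhibitor of nitric oxide synthase, rose by 3.50 ± 0.45 and Armcx4 by 3.77 ± 0.49 (adjusted p = 0.0435 for each). The metallothionein Mt1 fell by −2.49 ± 0.35 (adjusted p = 0.0486), and in smooth muscle or pericyte-like cells, where no gene test was run and the clusters differed (167 and 3, and 48 and 128 cells), it was at 170, 101 and 315 CPM against 2368, 1902 and 2193. In fibroblast-like cells Mt1 went the other way (159, 244 and 164 against 139, 24.9 and 103 CPM). In macrophage-like cells the groups overlapped (478, 761 and 158 against 293, 138 and 156 CPM). Gdpd3 fell from 184 ± 103 CPM to 0 UMIs (adjusted p = 0.0435), at least 63.1-fold lower against a floor of 3 UMIs over the group. It was also at 4.51, 10.9 and 6.32 CPM in macrophage-like cells of basal-induced and 921, 199 and 121 CPM of luminal-induced libraries. In smooth muscle or pericyte-like cells Gdpd3 was at 0 CPM in each basal-induced library against 508, 199 and 89.5 CPM. The calls changed with each library left out: edgeR called 0 and 0 without basal-induced 1, luminal-induced 1 or luminal-induced 3 (372, 326 and 325 higher and 350, 252 and 313 lower at an unadjusted p under 0.05), 8 higher and 2 lower without basal-induced 2, 483 and 482 without basal-induced 3, and 0 and 1 without luminal-induced 2 (294 and 288 unadjusted). Adjusted p of Col13a1, Armcx4, Ddah1, Gdpd3 and Mt1 was 0.249, 0.249, 0.249, 0.249 and 0.252 without basal-induced 1, 0.193, 0.193, 0.193, 0.165 and 0.215 without luminal-induced 1, 0.222, 0.1997, 0.123, 0.123 and 0.123 without luminal-induced 2, and 0.288, 0.261, 0.261, 0.205 and 0.261 without luminal-induced 3; without basal-induced 2, Armcx4 (0.0664) and Mt1 (0.0563) were lost.

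Fn1 in smooth muscle or pericyte-like cells was at 1721, 1662 and 1145 CPM in basal-induced and 97.3, 73.9 and 117 CPM in luminal-induced libraries. In endothelial-like cells it was at 410, 948 and 326 CPM against 67.5, 23.8 and 98.5 CPM, without a gene call there. The groups drew both classes in unlike shares from their clusters. Fn1 overlapped between groups in fibroblast-like cells (1200, 1400 and 1983 against 998, 1703 and 1428 CPM) and macrophage-like cells (122, 170 and 316 against 0, 160 and 17.4 CPM). In macrophage-like cells (68, 106 and 22 basal-induced and 7, 24 and 16 luminal-induced cells), where no gene test was run, 3 class II genes chosen after their values were seen were as follows: H2-Eb1 at 2419, 1972 and 2775 CPM against 12349, 11746 and 10585 CPM, H2-Aa at 4041, 3368 and 5677 CPM against 8707, 10404 and 9821 CPM, and H2-Ab1 at 2582, 2332 and 3287 CPM against 5610, 5230 and 3505 CPM. H2-Ea was there at 108, 60.8 and 253 CPM against 0 in each luminal-induced library. These class II genes all lie on chromosome 17, where a difference of strain cannot be told apart from the induced cell type. TOMATO UMIs were found in 20.1%, 24.9% and 6.15% of keratin-only cells of basal-induced and 2.17%, 1.20% and 2.65% of luminal-induced libraries, thinned to 2000 UMIs. Of cells with both marker sets 10.98%, 18.2% and 8.21% held one against 6.98%, 4.83% and 3.37%. The groups overlapped among uroplakin-only cells (5.96%, 11.96% and 4.52% against 4.76%, 6.19% and 2.61%) and cells with neither (10.6%, 18.6% and 6.45% against 9.52%, 0% of 48 cells and 1.79%). In endothelial-like cells, kept only where epithelial UMIs were few, 0% to 4.95% held one at the same thinned depth. Their library medians were 2618 to 7755 UMIs against 6370.5 to 16336.5 in urothelial-like cells. Foxr1, at 5.25 ± 0.681 CPM in luminal-induced and 0.0256 ± 0.0265 CPM in basal-induced urothelial-like cells, is the annotation neighbour of Upk2, whose promoter drove Cre in the luminal-induced mice.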
